A study of Mus musculus with 4 samples.

How the data were processed

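The series measured RNA of mouse blastocyst-derived outgrowths on Affymetrix whole-transcript arrays. Per the labels' protocols, blastocysts were collected at 3.5 days post coitum from intercrosses of mice carrying 1 mutant copy of Tip110, cultured individually for 4 to 6 days in embryonic stem cell medium with knockout serum replacement, and genotyped. Tip110 is the gene Sart3, whose protein helps U4 and U6 snRNAs to re-form the U4/U6 particle during splicing. There were 4 arrays, 2 of wild-type and 2 of Tip110-/- outgrowths. In each genotype, replicate 1 was a pool of 3 outgrowths and replicate 2 a single outgrowth. The RNA collected came to 746 pg and 178 pg for wild-type and to 165 pg and 144 pg for Tip110-/-. The sample labels state that 144 pg was labelled for each array with the Pico whole-transcript kit, while the series' design text states 100 pg; which holds is not known.

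The deposited table holds log2 values for 72688 rows in 4 columns. The log base was inferred from the range of the values. Per the submitters' processing notes, Affymetrix Expression Console and Transcriptome Analysis Console were used, with no version or role stated. The normalization algorithm and the genome build are not given in the sources used here, so no coordinates are printed. Scanner files were not used here, and the table carries no detection calls.

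Rows were named through the platform annotation. Of 65956 transcript cluster rows, 30604 had 1 gene symbol, 2146 had several and 33206 had none. Symbols repeated within a row were counted once. Symbols were updated by Entrez ID where the mouse gene table of assembly GRCm38.p6 held it, which was so for 22818 rows. A further 6732 rows were controls: 155 ERCC, 23 antigenomic background, 1324 taken as exon controls, 5222 taken as intron controls and 8 spikes. The files mark the exon and intron controls only as positive and negative; their meaning comes from general knowledge of the platform. Rows with several symbols, rows with none and control rows were left out of the gene test. For 355 genes with more than 1 row, the row with the highest mean over the 4 arrays was kept, leaving 30142 genes, 18820 of them protein coding.

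Tests used R 4.3.3 and limma 3.58.1. Each gene was fitted with lmFit and eBayes with an intensity trend on the deposited log2 values, with genotype as the only term and no filter on level. P-values were two-sided and adjusted by Benjamini-Hochberg over the 30142 genes, with a threshold of 0.05. Genes at an unadjusted p under 0.05 and a difference of at least 2-fold were counted as a description of size. A contrast of the pooled against the single-outgrowth arrays was fitted in the same way. Tables were joined with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.

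Before the data were examined, 34 gene lists were fixed from textbook knowledge, with 819 entries of which 698 had a row. The 33 lists with at least 5 rows were tested with limma's camera at its preset correlation of 0.01, two-sided and adjusted over the lists. The mitochondrially encoded list had 2 rows and was not tested. Counts of members were also adjusted over the list alone. Alternatives were camera with an estimated correlation, camera on ranks, and fry.

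The genes named were set by a rule fixed at the same time. It takes Sart3, Pou5f1, Nanog and Sox2, the 12 largest differences in each direction, and up to 4 members with the smallest p from each list that passes or is described. Because no gene passed the adjusted threshold, the 12 places were filled by genes at an unadjusted p under 0.05 with no overlap between groups and a mean above the median row of the table. Predicted genes and names or biotypes of microRNAs, snoRNAs and pseudogenes were left out.

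The gene and list tests were tested on simulated data of 4 arrays and 30142 genes. Noise was drawn independently for each gene from limma's variance prior for the real arrays, equal in both groups. Of 50 genes changed by log2 1, 0 were called, against 9 of 50 at log2 2, 24 of 50 at log2 4 and 48 of 50 at log2 8, with 8 of 29942 unchanged genes called. Camera called 0 lists in simulated data with no change and both of 2 lists shifted by log2 1, and 0 of these 2 with an estimated correlation. The simulated genes were not correlated, so this does not check camera's preset correlation. The shares of genes called need not carry over: in the real arrays Trh, at -8.48, was not called (limma adjusted p = 0.287).

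Other settings tried were quantile normalization, centring of columns, cyclic loess, a filter at the median row, other variance priors, array weights, a replicate term, the mean of a gene's rows, all rows of the table, and each array left out in turn. The replicate number also separates pools from single outgrowths, and nothing in the labels says that equal numbers share a litter or day. The number of arrays limits the precision: with 2 per group, each SD rests on 2 values. The labels call the samples biological replicates.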

Results

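RNA from outgrowths of wild-type and Tip110-/- mouse blastocysts was compared on 4 arrays, 2 per genotype. An outgrowth forms when a blastocyst attaches in culture: trophoblast cells spread out around the descendants of the inner cell mass. In each genotype 1 array held a pool of 3 outgrowths and 1 array a single outgrowth. Signal is given on the log2 scale as deposited. The median signal of the antigenomic background rows was 2.83 and 2.82 in the wild-type arrays and 3.05 and 2.94 in the Tip110-/- arrays, and the median over genes was 4.21, 4.22, 4.45 and 4.32 in the same order, so differences that end near these levels understate the change. The median over control rows taken as exons of widely expressed genes was 9.80 and 9.66 in wild-type and 8.69 and 9.51 in Tip110-/-. It was lowest in the pooled Tip110-/- array. RNA per outgrowth was 249 and 178 pg in the wild-type arrays and 55 and 144 pg in the Tip110-/- arrays. It was lower in both Tip110-/- arrays, so its part in any difference cannot be told apart from that of genotype. The hybridization controls bioB, bioC, bioD and cre were higher in both Tip110-/- arrays than in both wild-type arrays, by 0.336 to 0.792. A technical difference between the arrays therefore cannot be told apart from genotype either.

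The comparison of genotypes asks which transcripts depend on Tip110 in the early embryo. As lists, genes of the pluripotent epiblast, of mitosis, of cholesterol and lipid synthesis, of DNA replication and of DNA methylation and chromatin were called lower by camera in the Tip110-/- outgrowths, at medians of -1.68, -1.76, -1.15, -0.81 and -0.95 relative to all genes. None of these calls was kept when the correlation between members was estimated from the 4 arrays (adjusted p = 0.389, 0.389, 0.368, 0.368 and 0.389 in camera). That setting also called 0 of 2 lists shifted by log2 1 in simulated data with uncorrelated genes. A lost call is therefore weak evidence against a shift of that size. How the setting treats larger shifts or correlated members was not tested. By fry 0 lists passed as well (smallest fry adjusted p = 0.163). Genes of trophoblast giant cells and placenta were called higher as a list, at a median of 0.42, a call that ended without wild-type replicate 2 (0.19, camera adjusted p = 0.214) or Tip110-/- replicate 2 (0.40, adjusted p = 0.253). Nanog, a core transcription factor of the epiblast, was at 13.56 and 15.19 in the wild-type arrays and at 10.10 and 4.15 in the Tip110-/- arrays. Placental prolactin-family genes such as Prl5a1, at 10.94 and 10.95 against 15.61 and 17.56, were among the largest differences in the other direction. No single gene passed the adjusted threshold, and the trophoblast call was not kept with an estimated correlation either (camera adjusted p = 0.764).

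Sart3, the gene that encodes Tip110, was measured first. Its signal was 4.94 and 5.98 in the wild-type arrays and 4.28 and 4.54 in the Tip110-/- arrays, means of 5.46 ± 0.74 (SD, n = 2) and 4.41 ± 0.18 (SD, n = 2). The difference was -1.05 ± 0.39 (SE), lower in both Tip110-/- arrays, and did not pass the threshold (limma adjusted p = 0.386). The labels do not say whether the probes of this row lie in the deleted part of the gene, so the value is a limited check of the labels. Without wild-type replicate 2 the difference was -0.53 and without wild-type replicate 1 it was -1.57.

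Over the 30142 genes, 0 passed the adjusted threshold in limma, with a smallest adjusted p of 0.154, for Dse and Cyct. At an unadjusted p under 0.05 there were 3817 genes, 2711 higher and 1106 lower, where 1507 would be expected by chance without a shift of whole arrays. The median difference of all genes was 0.15, so list medians are given relative to it and single genes as measured. With a difference of at least 2-fold added, there were 1365 genes, 460 higher and 905 lower in Tip110-/-, and 210 and 686 of these were protein coding. By the same moderated test, 564 of 29942 genes simulated without a change reached this mark. The simulated genes varied independently and held no shift of whole arrays, so 564 is not a fair count of no change for the 1365. Without moderation, which was not simulated, the arrays gave 556 genes, 142 higher and 414 lower. Centring each array on its median turned this split into 258 higher and 1157 lower. The split also moved with single arrays, to 883 higher and 816 lower without Tip110-/- replicate 1 and to 732 and 723 without Tip110-/- replicate 2. In 52.9% of genes both Tip110-/- arrays lay beyond both wild-type arrays, where chance gives 33.3%. Of these genes 12040 were higher and 3899 lower, the opposite balance to that of the 2-fold genes. The chance values assume no shift of whole arrays, but the gene median was 4.45 and 4.32 in Tip110-/- against 4.21 and 4.22 in wild-type. How much of either excess comes from that shift was not tested, so neither measures an effect of genotype. Across genes, which are not independent replicates, r was 0.969 between the wild-type arrays, 0.967 between the Tip110-/- arrays and 0.938 to 0.963 between genotypes.

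**Figure D1:**
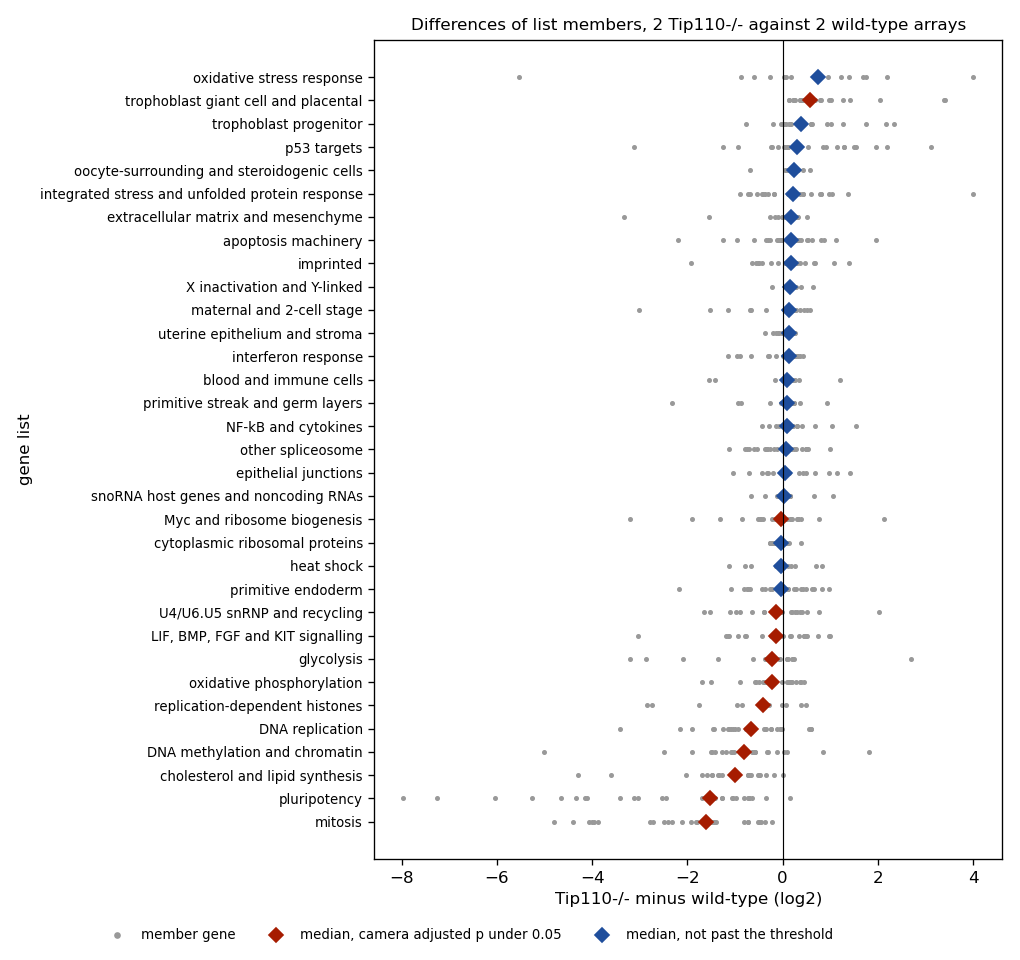
Difference between Tip110-/- and wild-type (log2, horizontal axis) for every member of the 33 tested gene lists (vertical axis), as grey points, with the list median as measured (not relative to all genes) as a diamond that is red where camera's adjusted p passed the threshold and blue where it did not. The pluripotency and mitosis lists lie farthest to the left, and the trophoblast giant cell and placental list is the only list with a positive median that passed.

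Pluripotency genes formed one of the strongest list differences. Of 29 measured members, 19 were lower at an unadjusted p under 0.05, 0 were higher and 10 did not pass; 17 passed when adjusted over the list alone and 0 over all genes. The list fell by camera (adjusted p = 1.0e-23), and the adjusted p was 0.389 with an estimated correlation. Pou5f1, the POU factor that maintains the inner cell mass, differed by -3.41 ± 0.84 (SE) and its partner Sox2 by -4.34 ± 0.85. Nanog differed by -7.25 ± 2.01. Nr0b1, a nuclear receptor of embryonic stem cells, differed by -7.97, the Nodal co-receptor Tdgf1 by -6.05, the growth factor Fgf4 by -4.15 and the chromatin protein Dppa4 by -3.04. The members were not equally affected: Sall4 differed by -0.34 and Zfp42 by -0.69, less than the spread between arrays. The list median was lower in both Tip110-/- arrays, at 7.28 in the pooled and 5.36 in the single outgrowth, against 8.51 and 8.82 in wild-type. Primitive endoderm markers, a list of the other inner cell mass lineage, did not pass (camera adjusted p = 0.119), with 1 of 26 members lower, the lipoprotein Apoe at -2.17, and 1 higher, the thyroxine carrier Ttr at 0.39, from levels near background. Without wild-type replicate 2 that list was called lower (median -0.51, adjusted p = 0.00024), and without wild-type replicate 1 its direction was the opposite (median 0.14, adjusted p = 0.545).

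**Figure D2:**
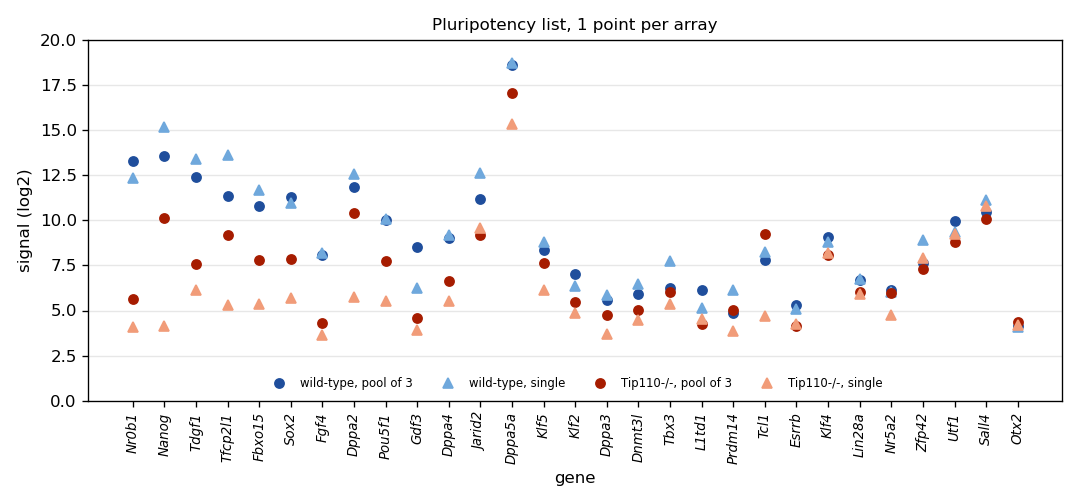
Signal (log2, vertical axis) of the 29 members of the pluripotency list (horizontal axis, ordered by difference), with 1 point per array: circles are pools of 3 outgrowths, triangles single outgrowths, blue wild-type and red Tip110-/-. In 24 of 29 genes both Tip110-/- arrays lie below both wild-type arrays, and for Nanog the single Tip110-/- outgrowth is at 4.15 and the pool at 10.10.

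The mitosis, DNA replication and replication-dependent histone lists were called lower by camera as well, and none of them with an estimated correlation. Of 31 mitosis genes, 19 were lower at an unadjusted p under 0.05 and 12 did not pass; 14 passed when adjusted over the list alone (camera adjusted p = 1.0e-23, and adjusted p = 0.389 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, differed by -4.41, Top2a, the topoisomerase of dividing cells, by -3.99, the kinase Aurkb by -2.78 and the spindle protein Hmmr by -2.71. Of 30 DNA replication genes, 3 were lower and 27 did not pass, and 1 passed when adjusted over the list alone (camera adjusted p = 5.5e-08, and adjusted p = 0.368 with an estimated correlation); the list median was -0.52 with quantile normalization. The 3 were the polymerase subunit Pole at -3.41, Mcm10 at -1.45 and the primase Prim1 at -1.44. Cdc45 differed by -2.16 and did not pass. Of 11 replication-dependent histone genes, 4 were lower and 1 higher, and 2 passed when adjusted over the list alone (median -0.57, camera adjusted p = 0.0012, and adjusted p = 0.389 with an estimated correlation); the median was -1.03 with rows above the median row only. H2ac20 differed by -2.84, H1f2 by -1.76, H1f5 by -0.85 and Hist1h4b, from a level near background, by 0.39. Near-identical histone copies can share probes.

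Among 20 genes of cholesterol and lipid synthesis, 7 were lower, 0 higher and 13 did not pass; 3 passed when adjusted over the list alone (camera adjusted p = 3.7e-12, and adjusted p = 0.368 with an estimated correlation). Hmgcs1, which makes HMG-CoA, differed by -4.31, the fatty acid synthase Fasn by -3.61, the squalene synthase Fdft1 by -1.36 and the mevalonate kinase Mvk by -1.27. In the DNA methylation and chromatin list 6 of 23 members were lower and 1 higher, with 0 adjusted over the list alone (camera adjusted p = 3.0e-07, and adjusted p = 0.389 with an estimated correlation). The dioxygenase Tet1 differed by -5.00, the corepressor Trim28 by -2.49 and Dnmt3l, which the pluripotency list also holds, by -1.42, while Tet3 differed by 1.82.

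A further 5 lists passed with smaller shifts and few members past the unadjusted threshold, and no call among them was kept under quantile normalization or cyclic loess. The medians of all 5, as measured, lay inside the central range of 10000 random lists matched on wild-type level, at percentile 47.7 for U4/U6.U5 snRNP, 6.11 for LIF, BMP, FGF and KIT, 78.2 for Myc and ribosome biogenesis, 5.34 for glycolysis and 29.0 for oxidative phosphorylation. In the U4/U6.U5 snRNP list, the group closest to the known role of Tip110, 2 of 24 genes were lower and 1 higher (median -0.28, camera adjusted p = 0.017, and adjusted p = 0.659 with an estimated correlation; 0 adjusted over the list alone). The U4/U6 protein Prpf31 differed by -1.65, Lsm4 of the ring on U6 snRNA by -1.53 and Zmat2 by -1.11, the last without passing, while Prpf4 differed by 2.02. This call ended without wild-type replicate 1 (median -0.19, adjusted p = 0.236) and without Tip110-/- replicate 1 (median -0.11, adjusted p = 0.288). In the LIF, BMP, FGF and KIT list, 2 of 24 were lower, the FGF feedback inhibitor Spry2 at -3.04 and the BMP target Id3 at -1.19 (median -0.28, camera adjusted p = 0.014, and adjusted p = 0.389 with an estimated correlation; 1 adjusted over the list alone). It ended without wild-type replicate 2 (median -0.22, adjusted p = 0.111) and without Tip110-/- replicate 1 (median -0.08, adjusted p = 0.122). In the Myc and ribosome biogenesis list, 2 of 27 were lower, Bop1 at -3.20 and Dkc1 at -1.90, and Myc itself was higher at 2.12 (median -0.17, camera adjusted p = 0.013, and adjusted p = 0.764 with an estimated correlation; 1 adjusted over the list alone). It ended without wild-type replicate 2 (median -0.20, adjusted p = 0.113) and without Tip110-/- replicate 1 (median 0.16, adjusted p = 0.628), and the median was -0.42 without Tip110-/- replicate 2.

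Among 20 glycolysis genes 3 were lower, the glucose transporter Slc2a3 at -3.21, the phosphofructokinase Pfkp at -2.88 and the pyruvate kinase Pkm at -2.10, and Vegfa, a hypoxia-responsive growth factor in this list, was higher at 2.70 (median -0.36, camera adjusted p = 0.0064, and adjusted p = 0.389 with an estimated correlation; 1 adjusted over the list alone). It ended without wild-type replicate 1 (median -0.12, adjusted p = 0.102), and the median was -0.19 without Tip110-/- replicate 1. Among 28 oxidative phosphorylation genes 2 were lower, Ndufv1 at -1.70 and Cyc1 at -1.51 (median -0.37, camera adjusted p = 0.0023, and adjusted p = 0.764 with an estimated correlation; 0 adjusted over the list alone). It ended without wild-type replicate 1 (median -0.08, adjusted p = 0.457).

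The trophoblast giant cell and placental list was the only list called higher by camera. Of 22 genes, 4 were higher at an unadjusted p under 0.05, 0 lower and 18 did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.764 with an estimated correlation). The surface protein Plet1 differed by 0.98, the matrix protease Mmp9 by 1.41, the pregnancy-specific glycoprotein Psg17 by 0.78 and the syncytin Syna by 0.36, the last near background. The call ended without wild-type replicate 2 (median 0.19, adjusted p = 0.214) and without Tip110-/- replicate 2 (median 0.40, adjusted p = 0.253), and the median was 0.85 without wild-type replicate 1, 0.72 without Tip110-/- replicate 1, 0.70 with quantile normalization and 0.63 with cyclic loess. Trophoblast progenitor genes did not pass (median 0.25, camera adjusted p = 0.506); 2 of 19 were higher, Gata2 at 2.16 and Ets2 at 2.34, and Tfap2a at 1.28 did not pass. Against random lists matched on wild-type level, the measured median of the giant cell and placental list lay at percentile 100, and so did that of the oxidative stress list, while the trophoblast progenitor list lay at percentile 99.7 and the p53 list at 99.1; camera did not call the oxidative stress, progenitor or p53 lists.

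The 12 largest differences toward lower signal were in Trh at -8.48, Nr0b1, Pla2g1b at -7.35, Nanog, Dse at -6.11, Tdgf1, Tdrd12 at -6.03, Fads2 at -5.83, Gsta4 at -5.55, Mylpf at -5.55, Sap30 at -5.47 and Cyct at -5.35. Trh encodes thyrotropin-releasing hormone and Fads2 a fatty acid desaturase. The 12 toward higher signal were Plau, the urokinase gene, at 5.94, the placental cathepsin Cts7 at 5.70, the prolactin-family genes Prl5a1 at 5.64, Prl8a9 at 5.53 and Prl8a1 at 5.10, Zfp954 at 4.54, the vasoactive peptide gene Adm at 4.12, the cystine transporter gene Slc7a11 at 4.01, Rnf225 at 3.74, Xlr at 3.63, Zfp419 at 3.58 and Prxl2c at 3.44. All are values that did not pass the adjusted threshold, with limma adjusted p from 0.154 to 0.393. Prolactin-family, cathepsin and zinc finger genes have close relatives whose transcripts can reach the same probes.

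**Figure D3:**
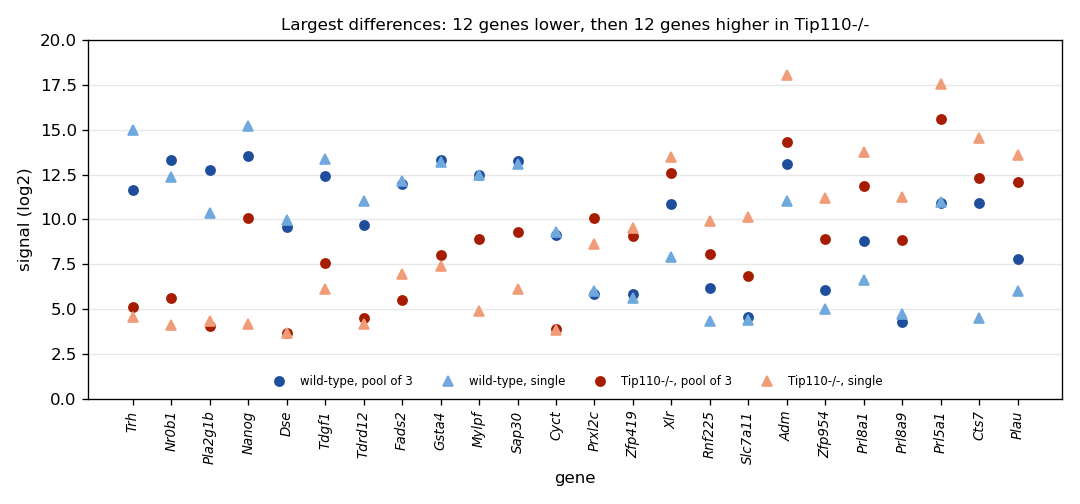
Signal (log2, vertical axis) of the 24 genes with the largest differences (horizontal axis), 12 lower and then 12 higher in Tip110-/-, with 1 point per array: circles are pools of 3 outgrowths, triangles single outgrowths, blue wild-type and red Tip110-/-. Cts7 differs between the wild-type arrays themselves, at 10.93 in the pool and 4.48 in the single outgrowth.

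Lists of death and stress genes did not pass. Of 25 p53 targets 4 were higher and 2 lower (median 0.15, camera adjusted p = 0.854): the death receptor gene Tnfrsf10b differed by 3.11 and Perp by 2.19, while the death receptor gene Fas differed by -3.12 and Ephx1 by -1.26. This list was called higher under quantile normalization (median 0.23, adjusted p = 0.035) and cyclic loess (median 0.34, adjusted p = 0.045). Of 28 genes of the apoptosis machinery 2 were higher and 2 lower (median 0.03, camera adjusted p = 0.573), with Fasl at 1.95 and Endog at -2.20. Of 15 oxidative stress genes 2 were higher, Slc7a11 and Gclc at 2.20, and 1 lower, Gsta4 (median 0.60, camera adjusted p = 0.900). The integrated stress and unfolded protein response (24 genes, median 0.06, adjusted p = 0.438) and heat shock (12 genes, median -0.18, adjusted p = 0.218) did not pass, but were called lower without Tip110-/- replicate 2 (medians -0.39 and -0.21, adjusted p = 0.029 and 0.045). Spliceosome genes outside the U4/U6.U5 group (28 genes, median -0.07, adjusted p = 0.076) and cytoplasmic ribosomal proteins (20 genes, median -0.18, adjusted p = 0.053) did not pass. Both were called lower without Tip110-/- replicate 2 (medians -0.29 and -0.31, each at adjusted p = 0.00398), and the ribosomal list also without wild-type replicate 2 (median -0.30, adjusted p = 0.019). Both were also called lower by camera on ranks (adjusted p = 0.013 and 0.0063), and the ribosomal list with array weights (adjusted p = 0.047) and without the variance trend (adjusted p = 0.047).

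Lists of further cell types and states gave no call. The primitive streak and germ layer list (18 genes, median -0.06, adjusted p = 0.793) held Lefty1 at -0.94 and Cer1 at 0.36, and the extracellular matrix and mesenchyme list (24 genes, median 0.03, adjusted p = 0.854) held Fn1 at -3.33 and Vim at -1.55. The maternal and 2-cell stage list (21 genes, median -0.0052, adjusted p = 0.930) held Zp3 at -3.01. The imprinted list (21 genes, median 0.02, adjusted p = 0.900) held Sgce at 1.08 and Impact at 1.41. Blood and immune markers (17 genes, median -0.05, adjusted p = 0.851), uterine markers (18 genes, median -0.01, adjusted p = 0.773) and markers of oocyte-surrounding cells (10 genes, median 0.08, adjusted p = 0.506) had 0 members at an unadjusted p under 0.05. The interferon (23 genes, median -0.02, adjusted p = 0.900), NF-kB and cytokine (19 genes, median -0.06, adjusted p = 0.725), epithelial junction (21 genes, median -0.11, adjusted p = 0.438), X inactivation and Y-linked (7 genes, median 0.01, adjusted p = 0.854) and snoRNA host (10 genes, median -0.11, adjusted p = 0.573) lists did not pass in camera either. The medians of the oxidative stress, apoptosis, integrated stress, matrix and imprinted lists lay above that of all genes where camera pointed lower, and those of the NF-kB, blood and uterine lists below it where camera pointed higher. As measured, the median difference was positive and the mean difference negative in the streak, other spliceosome, interferon, matrix, maternal and blood lists. Relative to all genes, as printed here, the medians of these lists were negative too, except that of the matrix list.

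Over all lists, 12 of 33 passed with camera's preset correlation, 11 lower and 1 higher. With an estimated correlation 0 passed (smallest adjusted p = 0.368), a setting that also missed both lists shifted in simulated data. On ranks 14 passed, and 0 by fry (smallest adjusted p = 0.163), which tests each list without comparing it with other genes.

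The contrast of pooled with single outgrowths has the same shape as that of genotype and was set beside it. It gave 0 genes past the adjusted threshold in limma and 460 at an unadjusted p under 0.05. With a 2-fold difference as well there were 249, 109 higher and 140 lower in single outgrowths, against 1365 for genotype. The third split of the 4 arrays gave 0, 611 and 333 genes. Both fits leave the genotype difference in the residual, and 460 and 611 lie below the 1507 expected by chance. The 249 and 333 are therefore no fair measure of no change for the 1365. With both factors in the fit, the 2-fold counts were 423 for pooled against single outgrowths and 1442 for genotype. A contrast of 2 against 2 arrays has 3 such splits, too few for a share under 0.05.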

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

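The tests of a single Tip110-/- array, of cell shares and of the background by GC content in this part were chosen only after the results were seen. The values that follow are Tip110-/- minus wild-type, on rows that no comparison of genes used, and were picked out because the signal there was higher in both Tip110-/- arrays than in both wild-type arrays. The median of the antigenomic background rows differed by 0.17, that of the intron control rows by 0.227 and that of transcript clusters with no gene symbol by 0.242. The median of the ERCC rows differed by 0.363 and the brightest ERCC row by 1.58. That median was 4.08 and 4.14 in wild-type and 4.62 and 4.32 in Tip110-/-, near the level of the intron control rows. Whether ERCC RNA was added to the samples is not known here. The spike rows dap and thr, which come from bacterial RNAs, differed by 2.20 and 2.94, while phe and lys of the same set differed by -1.06 and 0.88 with overlap between the genotypes, and the hybridization controls bioB, bioC, bioD and cre by 0.773, 0.792, 0.499 and 0.336. No explanation was tested for the spikes.

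The intron control rows were higher in the Tip110-/- arrays by 0.227 at the median. Intron rows exceeded transcript cluster rows of like level in all 4 pairs of a Tip110-/- and a wild-type array, by 0.094 to 0.269. Between replicates the same measure was 0.059 and -0.074, close in size to the smallest excess, 0.0942. Against that, the median of the dim transcript clusters with no gene symbol rose by 0.242, no less than that of the intron rows. Whether all dim rows shifted is therefore not settled. Background that rose unequally over GC content stays open and cannot be told apart from a change in introns, because the GC content of the intron probes was not used here; the largest upward shift of a background row was 0.311, rows of 6 to 12 GC bases shifted by 0.13 to 0.23, and the row of 3 GC bases shifted by -1.19. More retained intron RNA in outgrowths without a splicing factor is a hypothesis that these arrays leave untested.

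The pluripotency list was called lower by camera in the Tip110-/- arrays, with a median difference of -1.53 as measured, but not with an estimated correlation (adjusted p = 0.389) or by fry (adjusted p = 0.163). A level-dependent loss of signal is argued against: the median of -1.528 lies below the central range of -0.41 to 0.18 of 10000 random lists matched on wild-type level, and the mitosis list, at -1.612, lies below its own range of -0.47 to 0.20. A single Tip110-/- array as the source is argued against too, since the less affected array had a median of -1.217 against a matched range of -0.54 to 0.09. Trophoblast exceeded primitive endoderm markers by 0.493 to 1.07 in the 4 pairs of a Tip110-/- and a wild-type array, against at most 0.408 between replicates. A smaller share of epiblast cells as the only change would shift both alike only where both lie well above background. The median wild-type level was 5.07 for the whole endoderm list, against 8.16 and 6.09 for the trophoblast lists. The margin also rests on 2 replicate pairs. The comparison therefore cannot decide on this explanation, and a change in trophoblast stays open. A smaller share of epiblast and primitive endoderm cells together cannot be told apart from a change within cells, because the endoderm median ran from -0.72 to 0.218 over the pairs and its sign followed the wild-type array; loss of Tip110 itself stays open as well.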

How the results depend on the processing

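All alternatives here were listed before the data were examined. No gene passed the adjusted threshold in limma under any setting, with smallest adjusted p from 0.071 (no moderation) to 0.359 (all rows of the table). The 151 genes named besides Sart3 had 2093 alternatives; 2081 kept their direction, 12 did not, and 0 passed the threshold. Sart3 kept its direction, from -1.57 to -0.53 with an array left out. Genes at an unadjusted p under 0.05 and 2-fold numbered 1304 to 1731 with an array left out, 556 with no moderation and 2426 over all rows of the table, a larger number of rows. For the lone sample of a group, the fit assumes the spread of the other group. Lists past the threshold numbered 9 to 15 with an array left out, 0 with an estimated correlation, 0 by fry and 7 with rows above the median row only; the cause was not tested. The pluripotency, mitosis, cholesterol, DNA replication, chromatin and histone lists passed under each of 9 processing settings and 4 left-out arrays, with medians from -2.44 to -1.38, -2.01 to -1.43, -1.61 to -0.83, -0.90 to -0.52, -1.24 to -0.67 and -1.03 to -0.40 in that order. The count for pooled against single outgrowths was 423 with genotype as an added term. Signal near background limits what low rows can show.

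With the replicate number as a block, 0 genes passed (smallest adjusted p = 0.244), 1442 were counted at 2-fold, 12 lists passed and Sart3 was at -1.05 (adjusted p = 0.417). Deviations of arrays with the same number had a correlation of -0.090, and the numbers do not pair the samples.

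Some lists and genes turned direction, none of them past the threshold in the reported fit or where they turned; the cause was not tested. A list's direction is that of its test, and the values are its median relative to all genes, which can differ in sign. On ranks these were oxidative stress (0.60) and maternal (-0.0052). By fry these were streak (-0.061), other spliceosome (-0.067), apoptosis (0.027), integrated stress (0.061), interferon (-0.017), matrix (0.027), epithelial (-0.11), maternal (-0.0052), imprinted (0.020) and snoRNA host (-0.11). With quantile normalization these were Ifih1 (-0.012), Vcam1 (-0.0013), Ptprc (-0.025), Kdm5d (-0.15), other spliceosome (0.13), apoptosis (0.033), cytoplasmic ribosomal (0.011), integrated stress (0.18), heat shock (0.062), oxidative stress (0.85), epithelial (0.023), blood (-0.043), uterine (-0.035), imprinted (0.011) and snoRNA host (0.0061). With centred columns these were Kdm5d (-0.10), integrated stress (0.061), oxidative stress (0.60), blood (-0.049), uterine (-0.013) and imprinted (0.020). With cyclic loess these were Ptprc (-0.0087), Kdm5d (-0.12), other spliceosome (0.11), apoptosis (0.036), cytoplasmic ribosomal (0.031), integrated stress (0.23), heat shock (0.013), oxidative stress (0.81), epithelial (0.036), blood (-0.074), uterine (-0.056), imprinted (0.011) and snoRNA host (0.0055). With rows above the median row only, these were apoptosis (0.080), integrated stress (0.28), oxidative stress (0.68), epithelial (-0.032), blood (-0.11), imprinted (-0.023) and snoRNA host (-0.038). Without the variance trend these were oxidative stress (0.60) and imprinted (0.020). With the replicate block this was oxidative stress (0.60). With the mean of a gene's rows this was Rpl7a (0.084).

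With an array left out, ranges were -0.057 to 1.72 for Hspa1a, -0.035 to 0.17 for Kdm5d, -0.46 to 0.059 for Rpl8, -0.061 to 0.10 for NF-kB, -0.19 to 0.36 for X and Y, -0.058 to 0.065 for matrix, 0.0086 to 0.10 for imprinted, -0.39 to 0.31 for integrated stress, -0.081 to 0.055 for interferon, -0.019 to 0.038 for maternal, -0.0094 to 0.086 for oocyte-surrounding cells, 0.18 to 1.04 for oxidative stress, 0.038 to 0.42 for p53 and -0.51 to 0.14 for primitive endoderm.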

Other observations

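The tests on gene families in this part were made after the largest differences had been seen, on families chosen from them. The placental prolactin family had 21 genes with a row, 19 with a difference above the median of all genes (0.15) and 9 at an unadjusted p under 0.05, at a median of 0.62. Beside Prl5a1, Prl8a9 and Prl8a1, Prl7c1 was at 4.88 and 4.99 in wild-type and at 7.31 and 6.44 in Tip110-/-, and Prl2c5 at 15.25 and 14.40 against 16.00 and 16.74. The giant cell hormone genes Prl3d2 and Prl3d3 lay near the top of the scale in every array, at 18.37 to 19.01. The hypothesis that only the members picked for their size differ was argued against, since the median of the other 18, 0.435, lay above the matched range of -0.05 to 0.23; limma's camera gave these 18 an unadjusted p of 0.056 with an estimated correlation. The matched lists take genes as independent, so signal shared between related probes stays open here. Of 8 placental cathepsins 6 had a difference above the median of all genes, with a median of 0.37 inside the matched range of -0.07 to 0.40.

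A group of zinc finger genes around Rex2 lay in the other direction: 9 of 10 were lower at an unadjusted p under 0.05, at a median of -3.96. Rex2 was at 14.54 and 14.56 in wild-type and at 11.77 and 8.13 in Tip110-/-, Zfp981 at 14.15 and 15.00 against 11.19 and 8.12, and Zfp980 at 15.30 and 16.12 against 12.90 and 9.96, while Zfp983 differed by 0.31. Whether only the members picked for their size differ could not be decided here. The members taken out were set by hand from large differences already seen, not by the naming rule. The median of the 3 others, -2.37, lay below the matched range of -0.89 to 0.74, but it is the value of 1 gene, Zfp991. With an estimated correlation, limma's camera gave these 3 an unadjusted p of 0.257, and 1 of them is Zfp983. These genes are closely related and can share probes, so the values are not independent, and signal shared between related probes stays open as for the prolactin family.

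Genes beside Sart3 were tested for variants carried along from the strain of the mutant allele. Of the 100 nearest genes, 7% were at an unadjusted p under 0.05, against 12.7% of all others (one-sided Fisher's exact test, p = 0.976). The neighbours were drawn only from genes in the mouse gene table, while the others also included genes outside it. The shares are therefore not fully comparable, and at most they argue against a broad effect of such variants on these 100 genes. Variants that change a few of them would not raise the share, and genes farther along the chromosome were not covered, so both stay open.

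Xist was at 13.56 and 13.34 in the wild-type arrays and at 13.88 and 14.29 in the Tip110-/- arrays.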
